A study of Drosophila melanogaster with 4 samples.

How the data were processed

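The samples were chromatin immunoprecipitation and input libraries from Oregon-R embryos of Drosophila melanogaster, collected 14 to 16 h into development. The labels give 2 ChIP samples made with 1 antibody lot against H3K9acS10P, which recognises histone H3 acetylated at a lysine of its tail and phosphorylated at the neighbouring serine, and 2 input samples, each named as the background of 1 ChIP sample. Per the labels' protocols, embryos were fixed in formaldehyde, the chromatin was precipitated with the antibody and a bead suspension named PAS, and DNA was extracted after RNase and proteinase treatment.

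Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes, and the lists use the FlyBase r5 genome build, per the file headers. The program that called enriched regions, its threshold and its treatment of reads with several alignments are not given in the sources used here. The 3 deposited lists give each enriched region's sequence, first base, last base and score. 1 list belongs to ChIP replicate 1, 1 to ChIP replicate 2 and 1 to the whole series, and how the replicates were combined in the series-level list is not given in the sources used here. The score is the authors' own value for each deposited region, and its scale and log base are not given in the sources used here, so it was used only to rank, filter or describe regions within 1 list, and its ranks were correlated between replicates over overlapping regions. The lists hold no read counts, so the depth of each library is unknown, and no counting error of the reads can be stated. No list of the input libraries was used here.

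All numbers were computed from these lists with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Sequence lengths came from the file headers. Coordinates are 1-based and inclusive. The 5 large arms are X, 2L, 2R, 3L and 3R; 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet hold assembled heterochromatin, and U holds sequence without a chromosome position. 2 regions were called overlapping when they shared at least 1 bp. Overlap was compared with 1000 circular shifts of 1 list within each sequence (one-sided permutation test, smallest possible p = 0.001). Shifts keep the spacing of regions and ignore that some sequence cannot be aligned to. Shares of regions carry 95% Wilson intervals. Neighbouring regions are not independent, so these intervals are too narrow. Chromosome arms were compared in full 500 kb windows, with regions assigned by midpoint, by 100000 two-sided permutations of windows (smallest possible p = 1e-05). Window medians of score and width needed at least 5 regions. Benjamini-Hochberg adjustment covered the 12 X comparisons, which are 4 measures in 3 lists. U and the Het sequences were compared with the large arms in the same way, with a further adjustment over 6 tests, and sequences with fewer than 10 full windows in all were not tested. The 16 Het windows, pooled after the data were seen, come from 2RHet, 3LHet and 3RHet. Windows and regions are not replicates of embryos.

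The tests, samples and alternatives were fixed before the data were examined. The alternatives were an overlap of at least 50%, regions at or above the median score of their list, merging of regions 500 bp or less apart, large arms alone, 1 Mb windows, and each replicate list alone. For comparisons between sequences, the last of these is each replicate's own value, also given in the Results. The series-level list was not remade without a replicate. Comparisons of score, width and number of regions between X and the autosomal arms, shifts limited to 20 to 100 kb, the overlap per sequence, with its own 1000 shifts within those sequences, and the count of regions over 10 kb were added after the data were seen. Each value recomputed under an alternative took 1 label. Reversed is a change of sign, whether or not the threshold was passed. A reversed value was not counted again for crossing the threshold. Overlap values were labelled by their excess over shifted lists. Values labelled alike could differ widely. Covered bases of replicate 2 were 27.7 Mb, and 18.4 Mb at or above the median score, and were labelled alike. Named regions followed a fixed rule: the 10 highest-scoring and the 10 widest series-level regions that overlap both replicate lists, and the 5 highest-scoring regions of each replicate with no overlap in the other. Planned tests of genomic features and gene lists were not run, because the gene table at hand is on Release 6 of the genome and the lists are on r5; regions are therefore named by position and not by gene.

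The overlap and window tests were tested on simulated data. In the simulation of replicate 1 against replicate 2 with 4537 regions, an independent list overlapped 35.2% of regions, against 34.9% under shifts. A list with 60% of regions copied overlapped 65.9%, against an expected 65.6%. That expected value added chance overlap taken from the same shifts, so the match was partly given by construction. Each case used a single simulated list and 50 shifts. Regions were placed evenly at random, without the clustering of the real lists, and in the copied case only on 2L and 2R. In the simulation of X against the autosomal arms with 236 windows, 5.5% of 200 simulations without a difference were called, and 97% of those with 1.3-fold coverage on X. These simulations shuffled the covered shares among windows, so a rate near 5% without a difference was given by construction. Shuffling removes any likeness of neighbouring windows, so its effect on the test was not examined. Score, number and width of regions were not simulated.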

Results

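Enriched regions of H3K9acS10P were available for 2 ChIP replicates and for the series as a whole in embryos 14 to 16 h old. The epitope joins a lysine acetylation known from active genes with a serine phosphorylation known from mitotic chromosomes and, in interphase, from the kinase JIL-1, which is denser on the male X. The design gives 2 ChIP and 2 input samples and no treatment. The questions it allows are how far the replicates agree and where on the chromosomes the mark lies. Nothing in the labels says that the replicates came from separate embryo collections, so the spread between them may be technical. With 2 replicates, an exact two-sided sign test across them cannot give a p under 0.5, and none was run.

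H3K9acS10P formed regions of a few kilobases over much of the large chromosome arms. The series-level list held 15374 regions that covered 37.5 Mb, or 30.9% of the 5 large arms. Replicate 2 held 10280 regions covering 27.7 Mb, and replicate 1 held 4619 regions covering 10.9 Mb. The mean over replicates was 7450 ± 4003 regions (SD, n = 2), and the covered share of the large arms was 16.0% ± 9.92 (SD, n = 2). Replicate 2 thus held 2.23 times as many regions and 2.55 times as many covered bases as replicate 1. The median region width was 1756 bp in the series-level list, 2070 bp in replicate 1 and 2006 bp in replicate 2. The narrowest region was 1001 bp in the series-level list and 1301 bp in both replicate lists. Regions over 10 kb numbered 187 in the series-level list, 112 in replicate 2 and 4 in replicate 1, and 502, 270 and 11 when regions 500 bp or less apart were merged. In each list, wide regions scored higher than narrow ones. The median score was 0.99 in the widest 10% of regions of both replicate lists, against 0.65 in the narrowest 10% of replicate 1 and 0.58 in the narrowest 10% of replicate 2.

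The replicates marked the same places far more often than shifted lists did, and most of the disagreement came from regions called in replicate 2 alone. Of the 4619 regions of replicate 1, 4022 overlapped a region of replicate 2, a share of 87.1% (95% Wilson interval 86.1 to 88.0%). Shifted lists gave 37.2% on average and 45.9% at most (permutation p = 0.001). Of the 10280 regions of replicate 2, 3698 overlapped replicate 1, a share of 36.0% (35.1 to 36.9%), against 17.3% under shifts (permutation p = 0.001). The replicates shared 9.09 Mb, which was 83.6% of the bases of replicate 1 and 32.8% of those of replicate 2. The Jaccard index was 0.308, against 0.0692 under shifts. When shifts were limited to 20 to 100 kb, so that regions stayed in their part of an arm, the expected share rose to 43.4% for replicate 1 and 20.1% for replicate 2, still below the observed values (permutation p = 0.001 for both).

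Overlap was higher among high-scoring regions. With each replicate list divided into 10 classes of score, 94.6% of the highest class of replicate 2 overlapped replicate 1 (95% Wilson interval 93.1 to 95.9%), against 23.5% of the lowest class (21.0 to 26.2%) and 15.4% of the class next to it (13.3 to 17.7%). In replicate 1 the share was 97.2% in the highest class and 81.2% in the lowest. The highest class was also wider than the lowest, with medians of 4429 and 1504.5 bp in replicate 2 and 3180.5 and 1600 bp in replicate 1. Wider regions meet a 1 bp overlap more often by chance. No shifted share was computed per class, so score and width were not separated here. Regions of replicate 2 without a partner were narrower, with a median of 1727 bp against 3142 bp. Over the 4022 regions of replicate 1 with a partner, the scores of the replicates had a Spearman rho of 0.59 (permutation p = 1e-05, the smallest possible). This correlation runs across regions, which are not independent replicates.

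**Figure D1:**
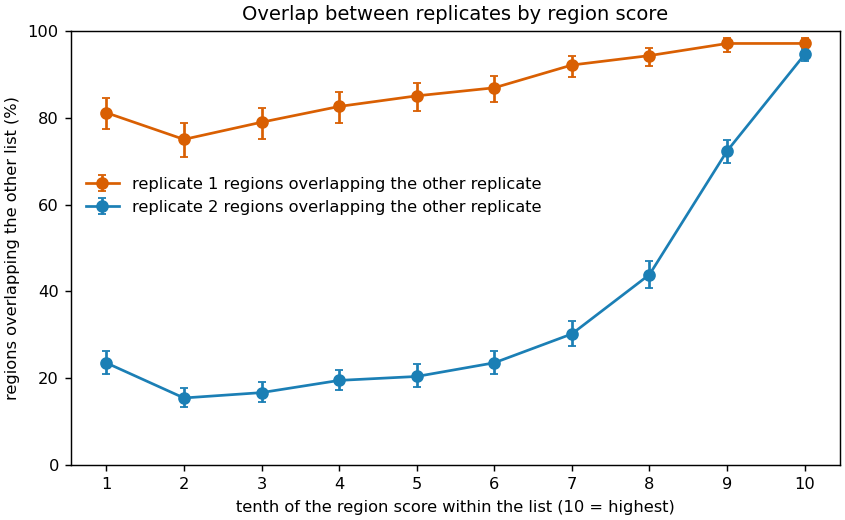
Share of regions that overlap the other replicate list by at least 1 bp (y axis, percent, bars are 95% Wilson intervals), by class of the authors' score within each replicate list (x axis, 10 classes, 10 is the highest). Replicate 2 lies between 15.4% in class 2 and 94.6% in class 10, and replicate 1 lies at 75.1% or above throughout.

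The broad landscape along the arms was shared as well. Across 236 windows of 500 kb, the covered shares of the replicates had a Spearman rho of 0.88 (permutation p = 1e-05), and within single arms rho lay between 0.86 on 2L and 0.90 on 3R. The window with the highest coverage in the series-level list was 2R 19500001 to 20000000, with 62.5% of bases covered, and 27.8% and 52.0% in replicates 1 and 2. On X, the window 1500001 to 2000000 was highest, at 58.7%. The lowest in the series-level list was 3L 24000001 to 24500000, at 2.66%, with 0.347% in replicate 1 and 1.97% in replicate 2.

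**Figure D2:**
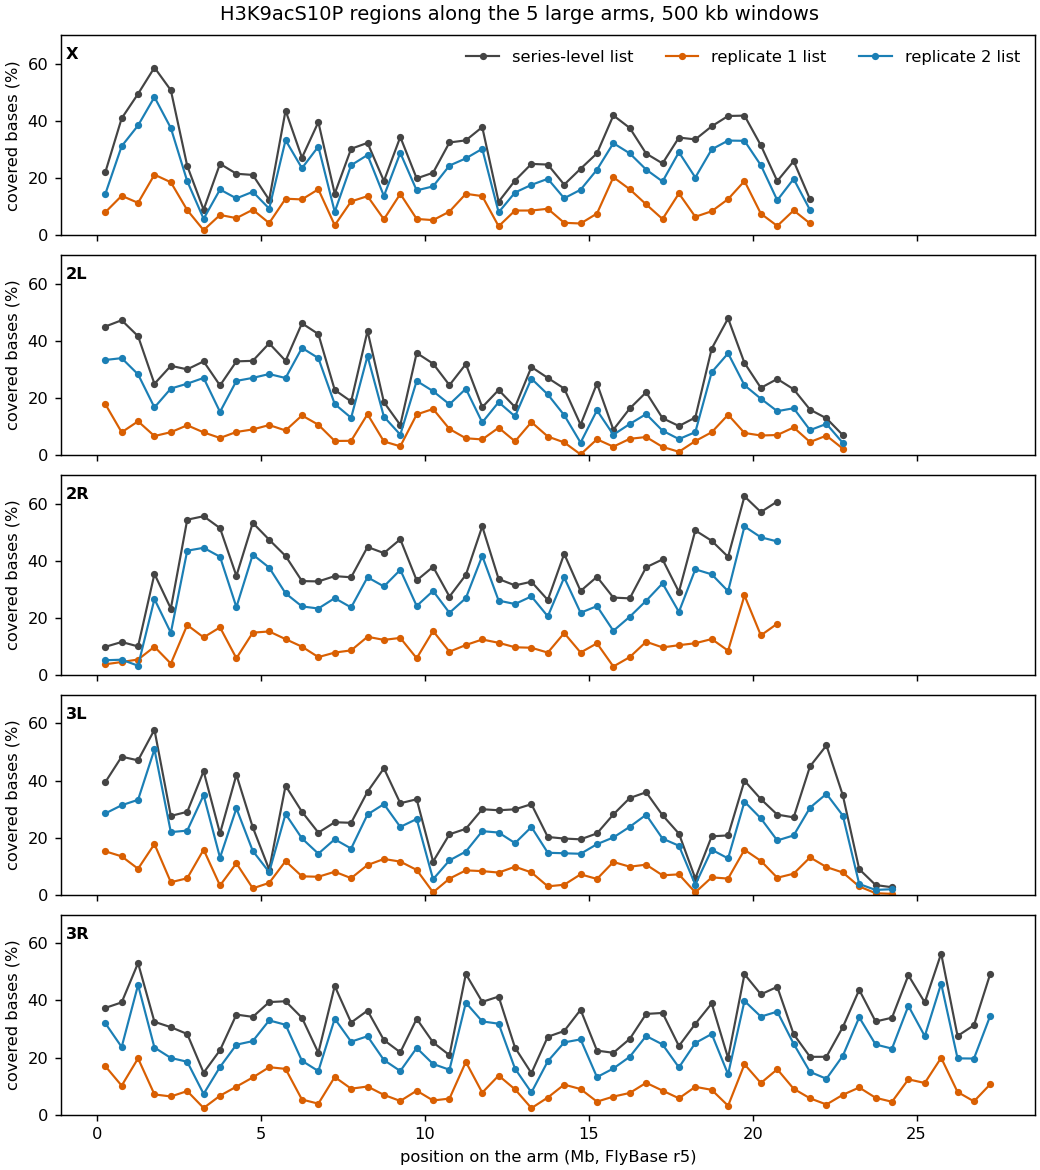
Covered share of bases (y axis, percent) in 500 kb windows along X, 2L, 2R, 3L and 3R (x axis, Mb of FlyBase r5) for the series-level list and the 2 replicate lists. The 3 profiles rise and fall together, from 2.66% at the end of 3L to 62.5% on 2R in the series-level list, with replicate 1 below replicate 2 in 235 of 236 windows.

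The series-level list contained nearly everything found in either replicate and much beyond. It overlapped 98.2% of the regions of replicate 1 and 96.9% of those of replicate 2. Of its own regions, 3457 overlapped both replicate lists, a share of 22.5% (95% Wilson interval 21.8 to 23.2%). Another 6146 overlapped replicate 2 only and 528 replicate 1 only. The remaining 5243, or 34.1% (33.4 to 34.9%), overlapped neither. Regions in both replicates were the wide ones, with a median of 3859 bp, and held 43.1% of the covered bases. Those in neither had a median of 1223 bp and held 18.5% of the covered bases. The median score was 0.70 in the first class and 0.45 in the second. Wide regions meet a 1 bp overlap with both lists more often by chance, and no shifted share was computed for these classes.

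The X chromosome had a higher mean window score than each large autosomal arm in all 3 lists. In the series-level list, the median score in X windows averaged 0.547 ± 0.0221 (SD over 44 windows), against 0.464 ± 0.0219 over 192 autosomal windows. Arm means on the autosomes lay between 0.461 and 0.468. X windows averaged 0.838 against 0.722 within replicate 1 and 0.790 against 0.651 within replicate 2 (permutation test, adjusted p = 3e-05 in each of the 3 lists). This comparison was chosen after the scores had been seen, and scores were compared only within a list. X had fewer regions, 104.6 per Mb against 130.6 in the series-level list (permutation test, adjusted p = 0.00022) and 69.2 against 88.9 in replicate 2 (adjusted p = 0.00056). The autosomal arms differed among themselves, from 110.6 per Mb on 2L to 150.4 on 2R in the series-level list and from 75.1 to 108.4 in replicate 2, so X lay close to 2L. In replicate 1 the numbers were 39.1 and 38.0 per Mb, with an adjusted p of 0.71 in the same permutation test. Among series-level regions at or above the median score the direction turned, with 79.7 per Mb on X against 58.1 (permutation p = 1e-05). This common threshold kept 1774 of 2325 X regions and 5598 of 12590 autosomal ones. The turn thus reflects the higher scores on X and is not separate evidence. Window medians of region width averaged 2225 bp on X against 1985 bp on the autosomal arms in replicate 2 (permutation test, adjusted p = 3e-05). In the series-level list and replicate 1 this difference did not pass the threshold (permutation test, adjusted p = 0.16 and 0.51). Among series-level regions at or above the median score, window medians of width were lower on X, averaging 2173 bp against 2555 bp (permutation p = 0.00014). The score difference there was 0.0358, against 0.0832 in the whole list (permutation p = 1e-05). Both values also depend on this score threshold, as wide regions scored higher than narrow ones.

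Regions over 10 kb made up a larger share of X regions than of autosomal ones in the series-level list and replicate 2. In the series-level list, 57 of 2325 X regions exceeded 10 kb, or 2.45%, against 130 of 12590 autosomal ones, or 1.03% (Fisher's exact test, two-sided, p = 2.4e-07). In replicate 2 the shares were 3.13% and 0.746% (p = 1.5e-12, Fisher's exact test). Replicate 1 had only 1 such region on X and 3 on the autosomal arms (p = 0.57, Fisher's exact test), so the difference was not detectable there. With neighbouring regions merged, 6.15% of X regions and 3.84% of autosomal ones exceeded 10 kb in the series-level list (p = 1.1e-05, Fisher's exact test). The planned measure, the covered share of bases, was 29.2% ± 11.2 on X and 31.5% ± 12.1 on the autosomal arms (SD over windows), a difference within the spread of windows (permutation p = 0.25, adjusted p = 0.33). It was -1.04 percentage points in replicate 2 and 0.967 in replicate 1, and neither passed the threshold (permutation test, adjusted p = 0.59 and 0.31). With regions at or above the median score alone, the direction turned, to 6.11 percentage points more on X (permutation p = 0.00014). That turn, too, reflects the common score threshold, which kept a larger share of the X regions.

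**Figure D3:**
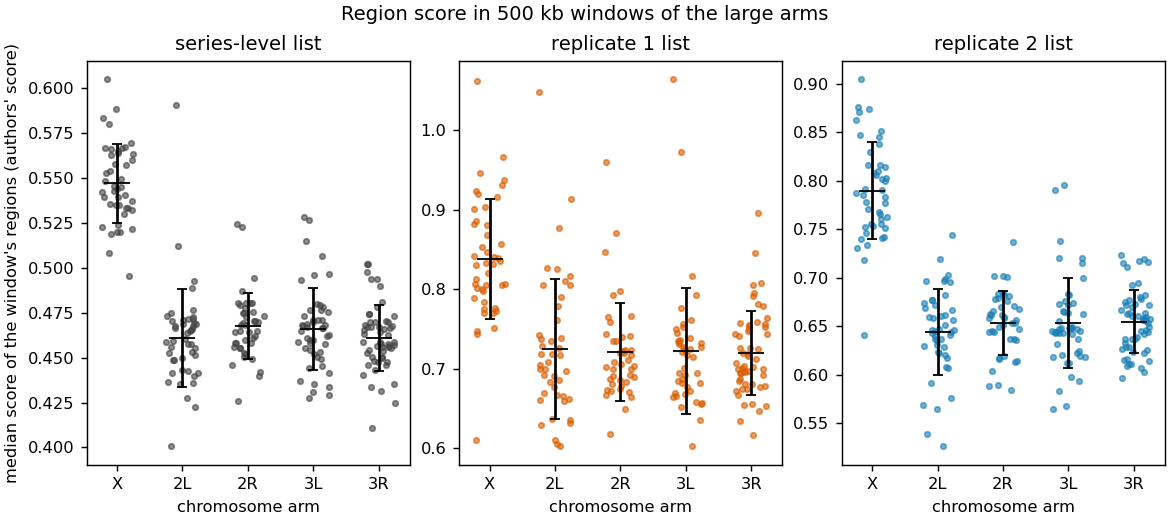
Median score of the regions in each 500 kb window (y axis, the authors' score, each panel with its own range that does not start at 0) on X, 2L, 2R, 3L and 3R (x axis) for each list. Points are windows, and black bars are their mean and SD. X averages 0.547 in the series-level list, 0.838 in replicate 1 and 0.790 in replicate 2, above every autosomal arm in each list.

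A smaller share of bases lay in regions on chromosome 4, the assembled heterochromatin and unplaced sequence than on the large arms. Chromosome 4, a small chromosome rich in heterochromatin, had 9.12% of its bases in series-level regions, against 30.9% of the large arms. The 6 Het sequences had 3.49% and U had 2.74%. The ratio to the large arms was 0.295 for chromosome 4, 0.113 for Het and 0.0886 for U in the series-level list. Over the replicates it was 0.424 ± 0.323 for chromosome 4, 0.0825 ± 0.0142 for Het and 0.0334 ± 0.0143 for U (SD, n = 2). The ratio for chromosome 4 thus differed between replicates, at 0.653 in replicate 1 and 0.196 in replicate 2. Its own covered share was 5.87% in replicate 1 and 4.52% in replicate 2. That of the large arms was 8.99% and 23.0%, so the ratio changed mainly through the large arms. In full 500 kb windows, U was covered to 2.75% ± 1.73 (SD over 20 windows) in the series-level list and the Het sequences to 3.47% ± 1.63 (SD over 16 windows), against 31.0% ± 12.0 over 236 windows of the large arms. Both differed from the large arms in each of the 3 lists (permutation test, adjusted p = 1e-05 over 6 tests, the smallest possible). Chromosome 4 held 2 full windows and was not tested. How well reads could be aligned to these sequences is not given in the sources used here.

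The share of replicate 1 regions with a partner in replicate 2 was lower outside the large arms, where chance overlap was lower too, in comparisons chosen after the data were seen. On chromosome 4, 13 of the 35 regions of replicate 1 overlapped replicate 2, or 37.1% (95% Wilson interval 23.2 to 53.7%), against 87.9% on the large arms (Fisher's exact test, adjusted p = 1.6e-11 over 6 tests). On the Het sequences it was 14 of 35 regions, or 40.0% (adjusted p = 9e-11, Fisher's exact test). On U it was 6 of 12 (adjusted p = 0.0018, Fisher's exact test). Among the regions of replicate 2, the share on chromosome 4 was 42.4% against 36.2% on the large arms and did not pass the threshold (adjusted p = 0.47, Fisher's exact test). It was 16.5% on Het and 11.1% on U (adjusted p = 0.00014 and 9.6e-05, Fisher's exact test). These tests compare shares without regard to chance. Shifted lists gave 37.8% on the large arms, 9.60% on chromosome 4, 4.00% on Het and 1.92% on U for replicate 1, so the observed shares were 2.33, 3.87, 10.0 and 26.1 times those of shifted lists. All 4 lay above the average of shifted lists (permutation test, adjusted p = 0.0013 on the large arms, Het and U and 0.005 on chromosome 4, over 8 tests). On chromosome 4 some shifted lists overlapped more than the real list, up to 48.6%. The excess over shifted lists was 50.1 percentage points on the large arms, 27.5 on chromosome 4, 36.0 on Het and 48.1 on U, and differences in excess were not tested.

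**Figure D4:**
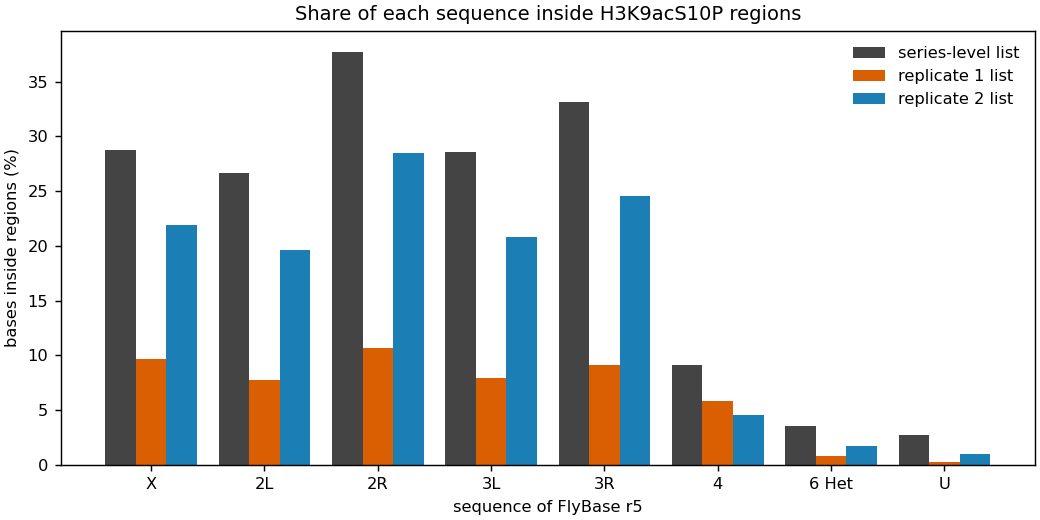
Share of bases inside regions (y axis, percent, from 0) for the 5 large arms, chromosome 4, the 6 Het sequences as 1 bar and U (x axis), for each list. In the series-level list the large arms lie between 26.6% and 37.7%, chromosome 4 at 9.12%, Het at 3.49% and U at 2.74%.

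The 10 highest-scoring regions shared by both replicates were all autosomal, with 4 on 2R and 2 each on 2L, 3L and 3R. They were compact, from 2.44 to 5.31 kb. The first was 3L 22068100 to 22072382, with a score of 2.05 in the series-level list, 2.13 in replicate 1 and 2.46 in replicate 2. Next came 2R 10102309 to 10105050, scoring 2.02, and 3R 26031607 to 26035607, also scoring 2.02. Below them lay 2R 17030178 to 17035490, scoring 1.91, and 2R 12456012 to 12459599, scoring 1.91. The remaining 5 scored from 1.83 to 1.86: 2L 18441686 to 18444129, 2L 10200072 to 10203964, 2R 20485442 to 20489260, 3L 1666702 to 1670355 and 3R 10727911 to 10730630. Each of the 10 was matched by a single region in each replicate.

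Of the 10 widest shared regions, 8 lay on X. The widest was X 19521267 to 19555845, which spanned 34.6 kb. It corresponded to 2 regions of replicate 2, 33.2 kb in all, and 9 regions of replicate 1, 23.6 kb in all. X 1758042 to 1786927 and X 1349376 to 1378243 each spanned 28.9 kb and were a single region in replicate 2, but 4 and 5 regions in replicate 1. The other X regions were 6707915 to 6732232, 513269 to 537468, 21208478 to 21232408, 19367732 to 19391366 and 20261745 to 20285131, from 23.4 to 24.3 kb wide. The 2 autosomal ones were 2R 13418383 to 13443412, of 25030 bp, and 3L 5743177 to 5766596, of 23.4 kb. They corresponded to 2 regions each in replicate 1, and to 3 and 4 regions in replicate 2.

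The 5 highest-scoring regions of each replicate without a partner in the other lay on unplaced or heterochromatic sequence. In replicate 1, 4 of the 5 were on U, led by U 7619797 to 7621407 with a score of 3.46, and the other was 3LHet 261452 to 263143 with a score of 1.85. In replicate 2, 4 of the 5 were on U, led by U 5464882 to 5466304 with a score of 3.34, and the other was 2RHet 226518 to 227823 with a score of 2.96. All 10 were under 2 kb wide. The other U regions of replicate 1 were 3109382 to 3110749, 8878581 to 8880555 and 5146802 to 5148344, scoring from 2.17 to 3.35. Those of replicate 2 were 9821624 to 9822976, 4992263 to 4993689 and 1386553 to 1388235, scoring from 2.44 to 3.22. In each replicate, all but the lowest of these 5 scores exceeded that replicate's score at every shared region named above.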

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

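The shifts of 20 to 100 kb and the comparisons of score, width, number and regions over 10 kb on X, with all their alternatives, were chosen after the data were seen, and the other alternatives before. The excess of replicate overlap over shifted lists, the score correlation and the higher score on X kept their direction and their side of the threshold under every alternative run: 83.7 to 87.9% of replicate 1 regions and 28.1 to 37.2% of replicate 2 regions overlapped, the Jaccard index was 0.282 to 0.310, rho was 0.67 with 50% reciprocal overlap, and the X score difference within the series-level list was 0.0832, 0.0835 in 1 Mb windows and 0.0358 among regions at or above the median score, where the threshold acts on the score itself. Each recomputed value took 1 label: 43 alike, 20 moved, 6 reversed in sign, 2 newly past the threshold and 1 no longer past it. Merging raised the number of regions over 10 kb to 502, 11 and 270 in the series-level, replicate 1 and replicate 2 lists, by construction. On X the share of such regions was 1.42 percentage points higher in the series-level list and 2.32 after merging. The difference was 2.38 in replicate 2 and 0.0339 in replicate 1, where the threshold was not passed. Keeping regions at or above the median score left 7688, 2310 and 5140 regions in the series-level, replicate 1 and replicate 2 lists, by construction, and 24.6 Mb in the series-level list. It lowered the support in at least 1 replicate list from 65.9 to 60.1%. It also turned the covered difference of X to 6.11 percentage points and the number of regions to 21.6 more per Mb, as a common score threshold retains more of the higher-scoring X regions (79.7 per Mb against 58.1), and the width difference to -382 bp (permutation p = 0.00014). Requiring 50% coverage lowered support in both lists from 22.5 to 16.5% and in at least 1 list to 64.0%. With 1 replicate left out, that support was 25.9% without replicate 2 and 62.5% without replicate 1. The covered X difference was -2.29 in the series-level list, -1.04 in replicate 2, 0.967 in replicate 1 and 0.979 for bases in both lists. None of these passed the threshold. The number of regions on X differed by -25.9 per Mb in the series-level list, -19.7 in replicate 2 and 1.09 in replicate 1. The mean window median of width on X differed by 71.6 bp, and by 78.3 bp in 1 Mb windows (permutation p = 0.046). It differed by 240 bp in replicate 2 and 34.1 bp in replicate 1. The ratio to the large arms was 0.653 in replicate 1 and 0.196 in replicate 2 for chromosome 4. It was 0.0925 and 0.0725 for Het and 0.0233 and 0.0434 for U. For bases in both lists it was 0.257 for chromosome 4, 0.0432 for Het and 0.0142 for U. For regions at or above the median score it was 0.178, 0.111 and 0.121. Where no construction is named, the cause was not tested. The lists give no read counts, so it could not be tested whether depth limits replicate 1. The planned tests of genomic features and gene lists were not run. No paired analysis was possible because the input samples, which share the replicate numbers of the ChIP samples, have no list of their own here.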

Other observations

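The comparisons of arm ends, spacing and empty stretches were chosen after the data were seen, while what each test of an explanation would show was written down before its result was seen. H3K9acS10P regions thinned out toward the centromere-facing end of the assembled sequence on 4 of the 5 large arms. In the series-level list, the 2 Mb at that end were covered to 16.9% on X, 14.7% on 2L, 16.7% on 2R and 11.9% on 3L. The rest of each arm was covered to 30.0%, 27.8%, 39.9% and 30.1%. 3R was the exception, with 40.6% against 32.5%. Each replicate list had the same direction on all 5 arms, with ratios of the centromere-facing part to the rest from 0.332 to 0.741 on the first 4 arms. On 3R the shares were 13.5% against 8.82% in replicate 1 and 31.2% against 24.0% in replicate 2.

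Regions also lay in clusters separated by long empty stretches. In the series-level list, 31.9% of gaps between neighbours on the large arms were 1 kb or shorter. In 200 random placements of the same widths it was 17.1% on average and 17.9% at most. Merging regions 500 bp or less apart left 12394 of the 15374 regions of this list, so short gaps may partly be splits of single stretches. How well reads could be aligned within the long gaps was not examined. There were 146 gaps of 50 kb or more, or 0.979% of gaps, against at most 0.0671% in random placements. In replicate 1 the share of such long gaps was 13.7% against 12.3% on average and 13.1% at most, a smaller excess than its share of short gaps, 12.8% against 4.17%. The longest stretch without a series-level region on each arm was X 21610242 to 21762400, of 152.2 kb, 2L 17804127 to 17953525, of 149.4 kb, 2R 2186812 to 2331264, of 144.5 kb, 3L 23472097 to 23606220, of 134.1 kb, and 3R 4672501 to 4756408, of 83.9 kb. Neither replicate had a region in these stretches except for 1 region of replicate 2 in that on 3L.

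The higher score on X extended along almost the whole chromosome. In the series-level list, 100% of the 44 X windows had a median score above the autosomal middle, and 43 of 44 did in each replicate list, so the difference was not confined to a few loci, though this says nothing of its cause. Width did not account for all of it. Within 10 classes of width, X regions of the series-level list still scored 0.0890 higher (95% bootstrap interval 0.0828 to 0.0954), against 0.0846 without classes. In the replicate lists the difference was smaller within classes of width. It was 0.0954 against 0.121 in replicate 1 and 0.116 against 0.129 in replicate 2. A loss of low-scoring X regions, as the lower X copy number of male embryos might cause, would not by itself add high-scoring ones. Yet X held 1.56 times as many regions per Mb above the autosomal 90th percentile of score (95% bootstrap interval 1.33 to 1.81). The ratio was 2.08 in replicate 1 and 1.86 in replicate 2. Such a loss alone thus did not account for the difference. Counts of high-scoring regions cannot show whether low-scoring ones were lost as well. The samples are not divided by sex and no biological explanation was tested, and an offset of the score itself from lower input coverage on X stays open, as no input values were used here.

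The difference in region number between the replicates is consistent with replicate 1 having detected a part of what replicate 2 did. The overlap of 87.1% (95% Wilson interval 86.1 to 88.0%) lay above the 80% set in advance for that explanation. The share was 87.9% on the large arms but below that bound on chromosome 4, at 37.1%, where replicate 1 held 35 regions and replicate 2 held 33, on Het, at 40.0%, and on U, at 50% of 12 regions. Joining or splitting of neighbouring regions did not account for the number, since replicate 2 still held 2.03 times as many regions after merging. Among the 10 widest shared regions, replicate 1 had more regions than replicate 2 in the 8 on X and fewer in the 2 autosomal ones. Depth, antibody recovery and a real difference between embryo collections stay open, as no read counts were used here and no test was made to separate them.

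Of the 5243 series-level regions seen in neither replicate list, 61.1% (95% Wilson interval 59.7 to 62.4%) were narrower than the 1301 bp of the narrowest replicate region, so a lower width minimum in the series-level list may account for much of this class. Only 4.62% of these regions lay on U or Het (4.08 to 5.22%). That share could not have been large, as the whole series-level list held 188 regions on U and 203 on Het. It therefore cannot decide whether repeats on these sequences add to this class. On U, 70.7% of series-level regions overlapped neither replicate list, and on single Het sequences 33.3 to 75%. On single large arms it was 30.2 to 34.9%. Why these shares differ was not tested, and repeats within the large arms were not examined. What separates the regions of this class that were 1301 bp or wider from the replicate lists was not tested.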
